A study of Penicillium oxalicum with 6 samples.

How the data were processed

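Messenger RNA was measured by RNA sequencing in mycelium of 2 strains of the filamentous fungus Penicillium oxalicum, with 3 libraries per strain. One strain, MuPOX00158, lacks the gene POX00158, and the other, Ku70, is labelled as a Ku70 mutant and serves as the comparison strain. Per the labels, mycelium of both strains was moved into liquid medium with 1% Avicel, a microcrystalline cellulose, for 24 h. Groups were taken from the strain label. The replicate numbers used below only name the libraries and follow the order of deposition. The labels do not say whether the 3 libraries of a strain came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

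The authors deposited 1 table per library with 2 values per gene. The first is an expected count, the number of reads that a probabilistic assignment gives to a gene, per the file headers. The second is an FPKM value, in which reads are scaled by gene length and library size, also deposited by the authors per the file headers. RSEM 1.2.12, Bowtie2 2.1.0, BWA 0.7.10-r789 and DESeq2 are named in the submitters' processing notes, without their roles. The genome build, the annotation and the strandedness of the counting are not given in the sources used here. The tables list no gene at 0, and the lowest listed expected count was 0.5. A gene missing from a library was therefore taken as having no read there. The tables name 9284 genes in at least 1 library, and 8137 in all 6. Expected counts are whole numbers except where reads match several genes, and 32 genes had a fractional count in at least 1 library. Values of those genes are uncertain, because their reads were split between similar sequences.

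The files pair no identifier with a gene name. A RefSeq table for this species was not used. It holds no symbol beyond locus tags, and its numbering did not match that of the files. Across 3734 genes with at least 100 reads in every library, the gene length in that table and the effective length implied by the deposited count and FPKM had a Spearman correlation of 0.01. No genomic positions are reported for this reason.

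Of 25 gene lists fixed before the data were examined, 19 needed product names and could not be tested. The other 6 rest on identifiers recalled from published work on this fungus: 10 cellulases, 7 beta-glucosidases, 8 xylanases, 3 amylases, 1 regulator of amylase genes (the only identifier in a list of cellulase regulators) and 1 regulator of sexual and asexual development. The enzyme classes below come from that recollection and not from the deposited files. The rule for the genes named was fixed at the same time. It took POX00158, the members of the enzyme lists (values for the 10 with the highest mean and for those with the largest change), up to 4 changed members of each other list, and the genes with the largest changes. The ranking for the latter required an adjusted p below 0.05, a mean of at least 10 CPM (counts per 1000000 reads) in the higher strain and no overlap between the strains' libraries. Where no table gives names, the rule allowed 2 identifiers that rose and 2 that fell beside POX00158. That limit was kept for the genes ranked by size of change, while the list members, whose classes were fixed beforehand, were named in addition, which departs from its wording. POX01764 and the runs of identifiers in the closing section were added after their values were seen.

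Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (a minimum count of 10, a minimum total of 15), which left 7757 genes. Libraries were scaled with TMM factors, and strains were compared with the quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05. Fold changes are MuPOX00158 over Ku70. The standard error (SE) of a log2 fold change is the fold change divided by the square root of its F statistic. CPM values use TMM-scaled library sizes without correction for gene length, so ranks by reads favour long genes, and are given as mean ± SD over 3 libraries. Lists with at least 5 tested genes were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over 3 lists. Alternatives were an estimated correlation and fry. Fisher's exact test compared each list with all tested genes and treats the genes as independent. Read shares of a list were compared with two-sided exact permutation tests, whose smallest possible p with 3 against 3 unpaired libraries is 0.1. Exchanging labels only within the letter pairs described below leaves 8 arrangements, and this test, added after seeing the data, gave its smallest p of 0.25 for the cellulase, beta-glucosidase and xylanase lists and 0.75 for the amylases (two-sided exact permutation).

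Totals ran from 2983815 to 3259601 expected counts per library, so that a count of 0 in all 3 Ku70 libraries allows up to 0.327 CPM (3 reads over the group). Such limits cover counting error only. Replicates were compared before averaging. The chi-square statistic per degree of freedom of their counts lay between 5.4 and 48.5 within strains, far above sampling noise, so each library counted as 1 sample. On data simulated from these means, library sizes and dispersions, with 200 of the tested genes changed, edgeR recovered 93% of 4-fold and 34% of 2-fold changes among 7703 genes tested, and 1.55% of its calls were false. The simulation gave 129 calls, against 2888 in the real data. The adjusted p threshold therefore falls at another unadjusted p, and these shares need not hold for the real fit.

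The titles end in a letter, F, S or T, used once in each strain. Whether the letters pair the libraries was checked from the correlation of deviations from the strain means. Same-letter libraries correlated at 0.15 (F), 0.22 (S) and 0.16 (T), each over 0.1 and each above every pair of different letters. The deviations sum to 0 within a strain, so these correlations are not independent, and 3 libraries per strain allow few matchings. The data therefore do not establish pairing. The letters were treated as possible pairs, on the data and not on a statement in the labels. The main fit has no block, and the fit with the letter as a replicate block is given beside a result where it changes a call. Other alternatives were DESeq2 1.42.0, plain library sizes, upper-quartile scaling, 2 other filters, each library left out in turn, and limma-trend on log2(FPKM + 1) of the deposited FPKM for genes with a mean FPKM of at least 1, with a pseudocount of 0.1 and without that filter as further settings.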

Results

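The series compared gene expression in a strain of Penicillium oxalicum that lacks POX00158 with that in a Ku70 strain. The stated aim was to learn how this gene, described as a phosphokinase, affects the transcript levels of cellulase and xylanase genes. Penicillium oxalicum is a soil fungus that secretes enzymes degrading plant cell walls. Ku70 is a protein of DNA end joining, and fungal strains without it are commonly used for gene targeting. Mycelium of 3 MuPOX00158 and 3 Ku70 libraries was sampled after 24 h on 1% Avicel, which as cellulose induces cellulase genes in such fungi. The libraries held 2983815, 3259601 and 3054173 expected counts for MuPOX00158 and 3064516, 3204464 and 3156585 for Ku70, over 8677 to 8750 genes each. The first principal component of log2 CPM separated the strains and held 82.7% of the variance. The second held 9.15%, and Ku70 replicate 1 stood apart from the other Ku70 libraries on it.

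POX00158 itself was nearly absent from the libraries labelled with its deletion. It had 4, 8 and 9 reads in the MuPOX00158 libraries and 1067, 569 and 763 reads in the Ku70 libraries. This corresponds to 2.19 ± 0.777 CPM in MuPOX00158 and 261 ± 77.5 CPM in Ku70 (SD, n = 3 each). The log2 fold change was -6.87 (SE 0.35, edgeR adjusted p = 5.04e-06). Every library thus carried the POX00158 level that its label calls for.

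Expression of 37.2% of the tested genes differed between the strains, in both directions. Of 7757 genes tested, 1442 rose and 1446 fell in MuPOX00158 (edgeR quasi-likelihood test, adjusted p below 0.05), and 4869 did not pass. Among the changed genes, 278 rose and 123 fell by 8-fold or more. A total of 50 genes lay under 1 CPM in every Ku70 library and over 10 CPM in every MuPOX00158 library, whereas 2 genes showed the reverse. Without Ku70 replicate 1 these numbers were 58 and 4, but leaving out a library can only keep or raise them. In edgeR without that library, 3323 genes changed in total. A total of 51.7% of the tested genes had no overlap between the 3 libraries of one strain and the 3 of the other, where chance gives 10%.

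**Figure D1:**
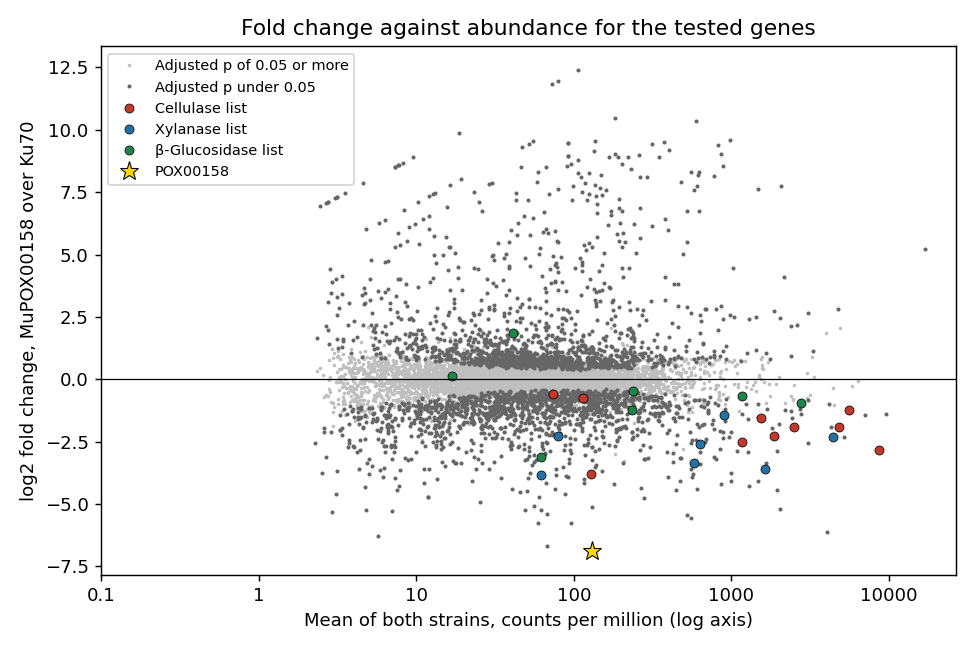
Fold change of the 7757 tested genes (vertical axis, log2 of MuPOX00158 over Ku70) against their mean level over both strains (horizontal log axis, CPM). Each point is a gene, darker where the edgeR adjusted p is below 0.05, and the coloured points are the members of the 3 enzyme lists and POX00158. The cellulase and xylanase genes lie below 0, while the largest rises belong to genes outside these lists.

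Cellulase genes were among the genes with the most reads in the Ku70 strain and fell broadly in MuPOX00158. Of 10 cellulase genes, 9 fell, 8 of them by more than 2-fold, and none rose. The median log2 fold change was -1.90. POX04786, a cellobiohydrolase gene whose product releases cellobiose from chain ends, had the most reads of all genes in Ku70, without correction for gene length. It dropped from 15273 ± 717 to 2115 ± 806 CPM (SD, n = 3 each; log2 fold change -2.85, SE 0.38, adjusted p = 0.000864). The second cellobiohydrolase gene, POX05587, fell less, from 7901 ± 906 to 3346 ± 985 CPM (log2 fold change -1.24, SE 0.32, adjusted p = 0.0169). Endoglucanases cut within the cellulose chain, and 6 genes recalled as members of this class fell by more than 2-fold. Among them POX07535 had the largest change of the list, from 239.8 ± 45.4 to 17.1 ± 6.58 CPM (log2 fold change -3.80, SE 0.30). POX05570 and POX05571, with neighbouring identifiers, had log2 fold changes of -2.51 and -2.27. POX01896, POX01166 and POX06147 had log2 fold changes of -1.91, -1.90 and -1.53. The smallest significant decrease was that of POX06983, at -0.74, a list member whose class is left open here. POX02740 had a log2 fold change of -0.60 (SE 0.22) with an adjusted p of 0.0706. In Ku70, 7 of the 10 genes ranked within the 100 genes with the most reads, against 3 in MuPOX00158.

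As a group, the cellulase genes took 4.16 ± 0.627% of the reads in Ku70 and 1.08 ± 0.287% in MuPOX00158, with no overlap between strains (SD, n = 3 each; two-sided exact permutation p = 0.1, the smallest that 3 against 3 unpaired libraries allow). Cellulase genes were lower relative to other genes in camera (adjusted p = 1.28e-06 with the preset correlation), a call that was lost with an estimated correlation (adjusted p = 0.151 with an estimated correlation). Fisher's exact test found more decreased genes in the list than among all tested genes, 90% against 18.6% (adjusted p = 1.33e-05). This test takes the genes as independent, whereas their estimated correlation was 0.811, so its p overstates the evidence. Adjusted over the list alone, all 10 genes fell. The calls of POX05587 and POX06983 were lost without MuPOX00158 replicate 1 (edgeR adjusted p = 0.0832 and 0.0595) and without MuPOX00158 replicate 3 (0.0744 and 0.0608), which left 7 of the 10 genes lower. Without MuPOX00158 replicate 2, POX02740 passed as well (0.00983). In that library the cellulase genes took 1.37% of the reads, against 0.798% in MuPOX00158 replicate 1 and 1.06% in MuPOX00158 replicate 3.

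**Figure D2:**
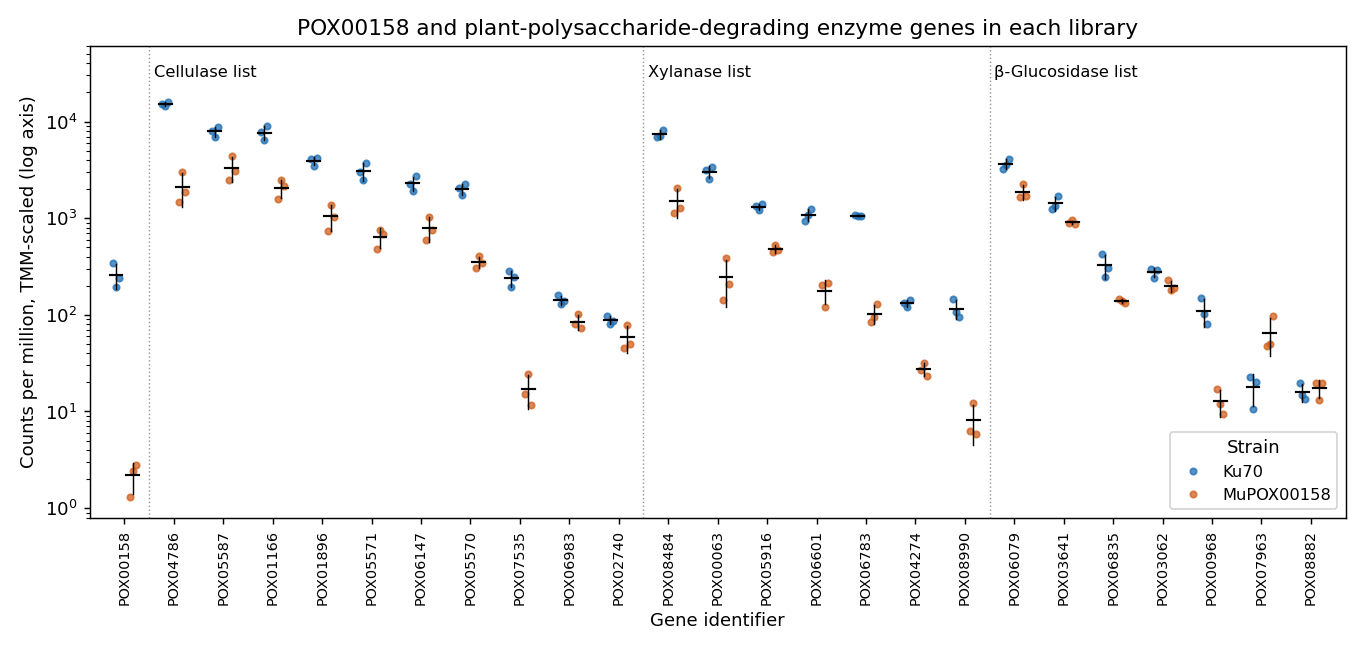
Level of POX00158 and of the cellulase, xylanase and beta-glucosidase genes in each library (vertical log axis, TMM-scaled CPM; 3 points per strain, horizontal bars for means, vertical bars for the SD). The libraries of the 2 strains do not overlap for any of the 10 cellulase and 7 xylanase genes, with the MuPOX00158 libraries lower in each. Of all tested genes, 51.7% show no overlap in either direction. POX02740 is parted narrowly, by 79.3 CPM in MuPOX00158 replicate 2 against 81.3 CPM in Ku70 replicate 2.

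Xylanase genes, whose products cut the main chain of xylan, fell in all 7 members analysed. All 7 decreased by more than 2-fold, with a median log2 fold change of -2.60, and the count was 7 whether adjusted over all genes or adjusted over the list alone. An eighth member of the list, POX00055, was listed in no library and was not analysed here. Whether it had no read or was recalled wrongly cannot be told. POX08484, the xylanase gene with the most reads in Ku70, fell from 7389 ± 744 to 1499 ± 497 CPM (SD, n = 3 each; log2 fold change -2.30, SE 0.32, adjusted p = 0.00115). POX00063 fell from 3008 ± 430 to 246.8 ± 126 CPM (log2 fold change -3.61, SE 0.40, adjusted p = 0.000358). POX06783 dropped from 1060.4 ± 12.2 to 103 ± 22.8 CPM (log2 fold change -3.36, SE 0.22). The largest fold change was that of POX08990, from 115 ± 25.7 to 8.12 ± 3.57 CPM (log2 fold change -3.82, SE 0.31). POX06601, POX04274 and POX05916 had log2 fold changes of -2.60, -2.27 and -1.45. Each of these 7 calls held in every library left out and in every other alternative computed.

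The xylanase genes took 1.37 ± 0.177% of the reads in Ku70 and 0.26 ± 0.0589% in MuPOX00158 (SD, n = 3 each; two-sided exact permutation p = 0.1). The list was lower in camera (adjusted p = 1.28e-06 with the preset correlation), and this call too was lost with an estimated correlation (adjusted p = 0.0706 with an estimated correlation). All 7 genes tested fell, against 18.6% of tested genes (Fisher's exact test, adjusted p = 2.32e-05). Here too the test takes the genes as independent, whereas their estimated correlation was 0.173.

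Beta-glucosidase genes, whose products split cellobiose into glucose, changed in both directions. Of 7 genes, 4 fell, 1 rose and 2 did not pass, POX03062 (log2 fold change -0.46, edgeR adjusted p = 0.0668) and POX08882 (0.14, adjusted p = 0.697). Adjusted over the list alone, 5 fell and 1 rose. POX06079, with the most reads of the list in Ku70, fell from 3649 ± 433 to 1874 ± 347 CPM (SD, n = 3 each; log2 fold change -0.96, SE 0.25, adjusted p = 0.0188). POX06835 had a log2 fold change of -1.23 and POX00968 one of -3.12, both past the test. POX07963 rose from 17.9 ± 6.42 to 65 ± 27.2 CPM (log2 fold change 1.86, SE 0.36, adjusted p = 0.00551). POX03641 had a log2 fold change of -0.65 and an edgeR adjusted p of 0.0382, which became 0.0807 with the replicate block, leaving 3 genes lower, 0.0584 with plain library sizes and 0.0675 without MuPOX00158 replicate 2. Without MuPOX00158 replicate 1 or 3 or Ku70 replicate 3, 2 of the 7 genes remained called lower, POX06835 and POX00968. Without Ku70 replicate 2, POX03062 passed as well (0.0407), which made 5 genes lower. The genes took 0.567 ± 0.0739% of the reads in Ku70 and 0.329 ± 0.0294% in MuPOX00158, with no overlap (two-sided exact permutation p = 0.1). Of the list 57.1% fell, against 18.6% of tested genes, which did not pass (Fisher's exact test, adjusted p = 0.0522). Across the list, the median log2 fold change was -0.65 and the camera test did not pass (adjusted p = 0.0528, and 0.151 with an estimated correlation).

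Of 3 genes of starch-degrading amylases, none fell, and POX09352 rose from 10.8 ± 4.08 to 32.4 ± 12 CPM (SD, n = 3 each; log2 fold change 1.57, SE 0.36, edgeR adjusted p = 0.0111). Adjusted over the list alone, the count was the same. POX01356 had a log2 fold change of 0.91 (SE 0.51), which was 0.10 without MuPOX00158 replicate 2, and POX02412 one of -0.08 (SE 0.17), neither past the test. The amylase genes took 0.0311 ± 0.0149% of the reads in MuPOX00158 and 0.0204 ± 0.00607% in Ku70 (two-sided exact permutation p = 0.4). POX03890, which encodes a regulator of amylase genes and is the only identifier in the list of cellulase regulators fixed beforehand, had a log2 fold change of -0.34 (SE 0.41, edgeR adjusted p = 0.541). POX08415, a regulator of sexual and asexual development, had one of -0.47 (SE 0.21, adjusted p = 0.105). Each of these regulator lists holds 1 gene, so adjustment over the list alone leaves the unadjusted edgeR p. It was 0.426 for POX03890 and 0.0499 for POX08415, just under the threshold. With 3 genes in the amylase list and 1 in each regulator list, no list test was made.

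The 2 genes with the largest fitted rises had no read in Ku70. Fitted folds over counts of 0 depend on the prior count, so only lower bounds are given, and their rank among the genes that rose is not established. POX09468 was at 214 ± 14.2 CPM in MuPOX00158 (SD, n = 3) and had no read in any Ku70 library, and was thus at least 653-fold higher against the floor of 3 reads over the group. POX09474 was at 158 ± 32.9 CPM against no read, at least 483-fold higher. Their edgeR adjusted p values were 4.40e-06 and 2.04e-05. After POX00158, the largest decreases were those of POX09354 and POX09580. POX09354 fell from 134 ± 39.8 to 1.25 ± 0.605 CPM (log2 fold change -6.69, SE 0.38). POX09580 fell from 11.3 ± 0.583 to 0.154 ± 0.153 CPM (log2 fold change -6.28, SE 0.56), but 4 of its 6 counts were fractional, so that its reads were shared with a similar sequence and its level is uncertain. Its MuPOX00158 counts were 0, 1 and 0.5, and without MuPOX00158 replicate 2 the log2 fold change was -8.12. None of these 4 identifiers has a name in the sources used here.

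The gene with the most reads in MuPOX00158 was POX01764, singled out after its values were seen. It rose from 898 ± 136 CPM in Ku70 to 33074 ± 1193 CPM in MuPOX00158 (SD, n = 3 each; log2 fold change 5.20, SE 0.40, edgeR adjusted p = 4.87e-05). It alone held 3.25, 3.40 and 3.54% of the reads in the 3 MuPOX00158 libraries. Its counts were fractional in 3 libraries, so part of its reads was shared with a similar sequence.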

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

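The count of 2888 changed genes stayed within 1.5 times its value under every other normalization, filter and tool tried: 2913 with plain library sizes (1625 higher, 1288 lower), 2840 with upper-quartile scaling, 2921 without a filter, 2816 with the stricter filter, 2980 with DESeq2, and 2757 to 2816 with limma on the deposited FPKM (1589 higher, 1227 lower with a pseudocount of 1 and the filter). The split was 1442 higher and 1446 lower in the planned fit, so it is less even in these 2 settings. With the letter as a replicate block it was 2909, of which 2694 were shared with the fit without the block. Leaving out 1 library gave 1984 genes (without MuPOX00158 replicate 3) to 3323 (without Ku70 replicate 1). No changed gene switched sign in any of these fits. Stricter thresholds lowered the count by construction, to 1754 (792 higher, 962 lower) with a 2-fold minimum and to 1720 (852 higher, 868 lower) at an adjusted p below 0.01. The 35 named genes gave 558 comparisons with alternatives. Of these, 543 kept their side of the threshold, 13 lost their call and 2 gained one. No comparison with a call in either fit reversed. Direction was not compared where neither fit passed. There POX02412 (log2 fold change -0.08) was at 0.04 and POX03890 (-0.34) at 0.01 without Ku70 replicate 1. The calls of the cellulase and xylanase lists were lost with an estimated correlation (adjusted p = 0.151 and 0.0706), and also with the block and an estimated correlation together (0.268 and 0.237), a setting added after seeing the data. They held in the other 11 settings each, the block included. The estimated correlation was 0.811 among the cellulase genes and 0.173 among the xylanase genes. The beta-glucosidase list, not called in the main test, passed with fry (directional 0.00259, mixed 0.000126), which does not compare it with other genes, with plain library sizes (0.0496) and without the genes with the most reads (0.0489), also a setting added after seeing the data; leaving out 1 library gave 0.0433 to 0.0920, and the cause was not tested. The block changed no other call of a named gene or list than that of POX03641. Of 9284 listed genes, 1527 had too few reads to be tested. In simulated data 2-fold changes were recovered less often than 4-fold changes, and what limits their recovery was not tested. The number of genes higher by 64-fold or more, 124 in edgeR, was 76 with limma on log2(FPKM + 1), whose pseudocount compresses changes of weak genes. The number lower by 64-fold or more, 4, was 9 without MuPOX00158 replicate 2 and 2 with log2(FPKM + 1).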

Other observations

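Tests of whether identifiers fall together by chance, of an extra copy of a segment and of a mislabelled sample were chosen after the results they bear on had been seen. The other tests were written down first. Of these, the test of shared reads was applied to a run of identifiers that was itself added after its values were seen. Some of the genes that changed by 2-fold or more in MuPOX00158 were grouped along the identifier numbers. The longest group was a run of 22 consecutive identifiers, POX05850 to POX05871, all of which rose by 2-fold or more, with a median log2 fold change of 8.11. Together they held 8250 ± 1178 CPM in MuPOX00158 and 159 ± 5.87 CPM in Ku70 (SD, n = 3 each), and 7 of them averaged under 1 CPM in Ku70. The tested genes on either side behaved differently: POX05847 fell by 2.73 on the log2 scale, and POX05873 had a log2 fold change of 0.34 that did not pass the test (edgeR adjusted p = 0.232). A second run of 11 genes, from POX09463 to POX09474, rose from 14.8 ± 4.0 to 5521 ± 309 CPM in sum, and holds POX09468 and POX09474, which had no read in Ku70. In all, 14 runs of at least 5 genes held 103 of the 1754 genes changed by 2-fold or more. Runs were formed over tested genes, so identifiers that were not tested were skipped and some runs are not unbroken. The run from POX08753 to POX08763, for example, holds 6 genes over 11 identifiers. Runs that fell included POX06599 to POX06603, 5 genes that contain the xylanase gene POX06601 and dropped in sum from 2956 ± 383 to 608 ± 49.1 CPM, and POX09357 to POX09361, whose sum dropped from 9190 ± 2704 to 158 ± 93.6 CPM.

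The Ku70 libraries differed among themselves in 2 adjoining runs, POX01170 to POX01176 and POX01178 to POX01183. The first summed to 1275, 6411 and 3912 CPM in Ku70 replicates 1, 2 and 3, and the second to 429, 4307 and 1923 CPM. The MuPOX00158 libraries lay between 16188 and 20725 CPM for the first and between 15247 and 19400 CPM for the second, above every Ku70 library. Of the 50 genes under 1 CPM in every Ku70 library and over 10 CPM in every MuPOX00158 library, 14 lay in runs that rose. These 50 genes held 0.48 ± 0.0753% of the reads in MuPOX00158.

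Whether identifiers follow the order of genes on chromosomes is not stated in the sources used here. The run of 22 genes was set against 3 explanations. Shuffling the identifiers 10000 times gave no run of rising genes longer than 7, so that chance order is argued against (p = 1e-04, the smallest these shuffles can give), and the log2 fold changes of neighbouring identifiers correlated at 0.34, against at most 0.04 in 1000 shuffles. The evidence is weaker for genes that fell, whose longest run was 6, while shuffled orders reached 8 (permutation test, p = 0.02). Reads shared between near-identical copies would leave fractional counts, and 0% of the run's genes had one. An extra copy of the segment would raise its genes by a few fold, whereas their median log2 fold change was 8.11 and the lower quartile 5.96. A candidate explanation is that these are neighbouring genes under joint control, low in Ku70 and high without POX00158. This stays a hypothesis, which an annotation giving positions for these identifiers would test; gene functions were not tested.

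The lower cellulase and xylanase levels were set against 3 explanations. The first is a few genes taking many reads in MuPOX00158. Removing the 10 genes with the most reads in each library and using plain library sizes would then end the decrease. The median log2 fold change of the 13 enzyme genes left was -2.20, with 12 of them still called lower. The 10 genes with the most reads held 8.95 to 9.12% of the reads in MuPOX00158 libraries and 8.63 to 9.77% in Ku70 libraries. Their removal could therefore shift fold changes only slightly and decides little. The genes removed included 4 enzyme genes, which ranked 1, 6, 7 and 8 in Ku70 and 34, 19, 37 and 69 in MuPOX00158. The Ku70 shares thus count enzyme genes that fell, so the likeness of the shares decides nothing. Genes that held at most 9.12% of the reads in a MuPOX00158 library could lower the others only slightly. This argues against the explanation for those 10 genes. A mislabelled library is argued against by POX00158, whose lowest Ku70 level was 69.5 times its highest MuPOX00158 level. A difference in growth state cannot be told apart from an effect of the deletion. The enzyme genes differed between 2 Ku70 libraries by a median of at most 10.9% of their change between strains, but the libraries of a strain need not be separate cultures, so this spread may hold no difference in growth, and the limit set beforehand for excluding growth state was not used. A difference in growth or cellulose use between the strains at 24 h, following from the deletion or from another change in the strain, may lower these genes and was not tested; the design holds 1 time, 1 carbon source and no complemented strain.

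The real split of the 6 libraries into 3 and 3 gave 2888 changed genes, and the highest count among the other 9 of the 10 possible splits was 0 in edgeR, so that 1 split reached the real value. The 3 other splits that also part every pair of same-letter libraries gave 0 as well. Unlike the real split, each of the other 9 mixes the strains, so the strain difference enters the spread within its groups. Their low counts were thus largely fixed in advance. With 10 splits no share under 0.05 is possible.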
